A study of Mus musculus with 9 samples.

How the data were processed

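Messenger RNA was sequenced from mast cells grown from the bone marrow of C57BL/6 mice, in 3 groups of 3 libraries. Per the labels' protocols, the cells were cultured for at least 4 weeks in medium with 30% WEHI-3 conditioned medium, a source of interleukin 3, and 20% fetal bovine serum, and stranded libraries were read as pairs of 2 reads of 101 bases. The Control libraries came from untreated cells. The BSA libraries came from cells sensitised with an antibody of the IgE class against dinitrophenyl and then exposed to dinitrophenyl coupled to serum albumin, the antigen that crosslinks the antibody on the high-affinity IgE receptor. The Taxinine libraries came from cells treated in the same way after 1 h with taxinine, a taxane diterpenoid from yew. The labels give no dose of taxinine, no length of antigen exposure, no vehicle and no group with taxinine alone, so differences between Taxinine and BSA include any effect of a solvent. They call the 3 samples of a group biological replicates without saying whether these came from separate animals or cultures. The p-values here therefore measure the spread between these samples, which may be technical.

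Reads were aligned with STAR 2.7.0f to the mouse genome, and mm10 and GRCm38 are the builds named, per the submitters' processing notes. The same notes name limma 3.11. The annotation, the counting program and its strand setting are not given in the sources used here. The deposited count table holds whole-number read counts for 15109 genes, although its name speaks of normalised values. Its column totals differ between libraries, and its distribution of small counts shows no mark of scaling and rounding, so the counts were used as unscaled. The deposited log2 table equals log2 of CPM (counts scaled to a common library total) plus 1, computed with plain library totals, to within 5.0e-05. It was not scaled by the trimmed mean of M values (TMM). The table was already restricted when deposited: every gene has a count in at least 4 libraries, the lowest total over the 9 libraries is 8 counts, and no gene of the mitochondrial genome is listed. Of the identifiers, 15106 are in the GENCODE M21 annotation of GRCm38, from which coordinates were taken.

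Total counts were 13712274, 14116976 and 13869250 in Control, 14005776, 13395131 and 11680348 in BSA, and 8975371, 10945236 and 13829804 in Taxinine replicates 1 to 3. At these totals a limit of 3 counts in 1 library corresponds to 0.192 to 0.347 CPM. Counting intervals and limits cover counting error only, since reads were not tagged by molecule.

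The main test was edgeR 4.0.16's quasi-likelihood test on the counts, with TMM factors, 1 fit over all 9 libraries and no replicate term, followed by Benjamini-Hochberg adjustment over the 15109 genes. A gene was called at an adjusted p under 0.05. The design written before the data were examined had planned limma on the deposited log2 values. It was replaced because the count table turned out to hold unscaled counts, and the planned fit was kept as an alternative, run with limma 3.58.1 in R 4.3.3. The planned filter, log2 CPM above 0 in at least 3 libraries, removed no gene. The comparisons, the gene lists, the rule for named genes and the alternatives listed as planned were also fixed before the data were examined. Fold changes are log2 values with their standard errors; group levels are CPM with TMM-scaled totals, as mean and standard deviation over 3 libraries. For a gene with no counts in a group, the fold is a lower bound against 3 counts over the whole group. For a gene with 1 to 3 counts in a group, the ratio of summed counts is given with its exact 95% interval.

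The 38 gene lists were written from general knowledge and covered signalling, secretion, stress, metabolism, growth and markers of other blood cells. The 35 lists with at least 5 members in the table were tested with camera at a preset correlation of 0.01, adjusted over these 35 lists, with estimated correlations and the rotation test fry as alternatives. Camera asks whether the members shift more than other genes, and fry whether they shift at all. Where many genes change, a call by fry therefore does not set a list apart. Lists for the interleukin 17 and tumour necrosis factor pathways are named in the title of the series, so their direction is not independent evidence. Genes named in the text are the 10 largest rises and the 10 largest falls among called genes with a mean deposited log2 value of at least 1 whose 2 groups do not overlap, predicted genes left out, up to 4 members with the smallest p of each list described, and 12 genes fixed in advance because they are mediators, receptors or regulators of mast cells. Any other named gene is said to have been chosen after its values were seen. Some genes that meet this rule are not reported here.

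The procedure was tested on simulated data with 50 changed genes at each of 4 fold sizes. The changed genes were drawn only from genes above a minimum of expected counts, so recovery among low-count genes was not measured. It recovered 64%, 94%, 100% and 100% of the genes changed by 1.25, 1.5, 2 and 4-fold for BSA against Control, with 5.94% false calls. For Taxinine against BSA it recovered 50%, 86%, 94% and 100%, with 2.75% false calls. For Taxinine against Control it recovered 66%, 76%, 98% and 100%, with 3.66% false calls. None of the 30 random lists was called. The simulated genes varied independently of each other, whereas the estimated correlation reached 0.817 in the ribosomal list. The random lists therefore do not measure false calls among correlated genes. Alternatives included other scalings, filters, pseudocounts and fold minimums, DESeq2 1.42.0, library weights, a replicate term, thinning to the smallest library, removal of a trend on transcript length and GC content, and leaving out each library. Comparisons that share libraries were set against 100 simulated sets of unchanged groups, and against 100 sets that keep the difference between Control and the activated groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.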

Results

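Transcript levels were measured in mouse bone marrow-derived mast cells, tissue-resident effector cells of allergy, in 3 untreated (Control), 3 antigen-activated (BSA) and 3 taxinine-pretreated, antigen-activated (Taxinine) samples. The title of the series names a programme of interleukin 17 and tumour necrosis factor genes in mast cells as the question. Total counts ranged from 8975371 to 14116976 per library, and 13803 of the 15109 genes had a count in all 9 libraries. The first principal component, 46.1% of the variance, separated the Control libraries (scores from -43.7 to -42.7) from the 6 activated ones (19.0 to 23.8). The second, 11.04%, separated BSA (11.7 to 19.2) from Taxinine (-32.7 to -5.89), with Taxinine replicate 1, the library with the fewest counts, at the lowest score. The biological coefficient of variation was 3.90%. Levels are CPM, the counts scaled to a common library total, as mean ± SD (n = 3), and log2 fold changes are given ± SE.

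The first comparison sets cells sensitised with IgE and given antigen against untreated cells, so it does not separate sensitisation from crosslinking of the IgE receptor. Nr4a3, an orphan nuclear receptor (GRCm38 chromosome 4, 48045153 to 48086447), showed the largest rise: 1172 ± 74.6 in BSA against 3.74 ± 0.420 in Control, a log2 fold change of 8.29 ± 0.07. The early growth response transcription factors Egr2 (chromosome 10, 67535475 to 67542188; 6.93 ± 0.06) and Egr3 (6.12 ± 0.06), Nr4a1 (6.28 ± 0.06) and the AP-1 subunit Fosb (5.42 ± 0.05) rose as well. Il6 (chromosome 5, 30013114 to 30019981) rose from 192 ± 16.4 to 942 ± 78.1, and Tnf (chromosome 17, 35199381 to 35202007) rose from 24.9 ± 1.53 to 356 ± 46.8. Il13, a cytokine of type 2 inflammation, rose from 11.6 ± 2.09 to 282 ± 39.9, and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 4.65 ± 0.08 on the log2 scale. Transcripts of the receptor itself and of the stem cell factor receptor did not pass the test: Fcer1a gave 4497 ± 177 against 4389 ± 88.6, and Kit gave 3947 ± 174 against 3748 ± 122 (edgeR's quasi-likelihood test, adjusted p = 0.514 and 0.121). Both were called lower with edgeR and total count scaling (-0.19 and -0.15), with limma on the deposited values (-0.19 and -0.15) and after quantile normalisation (-0.32 and -0.45), so their direction depends on the scaling.

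In all, 5144 of 15109 genes passed edgeR's quasi-likelihood test, 2450 higher and 2694 lower in BSA, and 940 of them changed at least 2-fold (556 higher, 384 lower). The groups did not overlap in 4775 of the called genes and in 42.9% of all genes, where chance gives 10% for 3 against 3. Trib1, a pseudokinase regulator of protein degradation (6.02 ± 0.17), the chemokine genes Ccl7 (5.97 ± 0.07) and Ccl4 (5.68 ± 0.07) and the receptor tyrosine kinase gene Mst1r (5.64 ± 0.35) completed the largest rises together with a pair of genes at the counting limit. Mst1r was close to that limit too, at 0.198, 0.064 and 0.0654 CPM in Control replicates 1 to 3, which is at most 3 counts in each. Csf2, the granulocyte-macrophage growth factor, had 163 counts in BSA and 2 in Control, a ratio of 102 (95% counting interval 27.7 to 848). The processed pseudogene Rpl23a-ps2 had 152 counts against 1, a ratio of 190 (33.6 to 7548), and its reads cannot be separated with certainty from those of its parent gene.

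All 20 measured members of the fixed list of antigen-induced cytokines rose (20 adjusted over the list alone), with a median log2 fold change of 1.85. Csf1, the macrophage growth factor, rose by 3.73 ± 0.06, Lif by 2.69 ± 0.06, Il1b by 1.31 ± 0.05 and Il4 by 1.03 ± 0.08. Of 17 chemokines, 12 rose and 0 fell (12 and 0 adjusted over the list alone), among them Ccl3 (3.90 ± 0.06) and Ccl2 (2.89 ± 0.06). Of 30 immediate early genes, 27 rose and 2 fell, the same counts as adjusted over the list alone. Targets of the transcription factor NF-kB had 17 members higher and 5 lower of 26 (19 and 7 adjusted over the list alone). The inhibitor genes Nfkbid (4.77 ± 0.05) and Nfkbiz (2.71 ± 0.05), Tnfaip2 (2.46 ± 0.05) and Tnfaip3 (1.45 ± 0.04) were among them, while Nfkbia rose by 0.81 ± 0.05. In the calcium and NFAT list, 11 of 21 rose and 0 fell (11 adjusted over the list alone). Rcan1, a calcineurin regulator, was at 3.73 ± 0.08 and Nfatc1 at 0.95 ± 0.04. Feedback regulators of the MAP kinase pathway had 17 of 26 higher and 2 lower (18 and 2 adjusted over the list alone), including Spry2 (3.07 ± 0.07) and Rgs2 (2.47 ± 0.04). These 6 lists were called by camera, with adjusted p from 1.21e-28 to 4.06e-05, and kept the call with estimated correlations (adjusted p from 0.0117 to 0.0443).

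Genes of glucose metabolism and hypoxia had 22 of 28 members higher and 1 lower (22 and 1 adjusted over the list alone). The stress gene Ndrg1 was at 2.71 ± 0.05, the glucose transporter Slc2a3 at 2.03 ± 0.04 and Vegfa at 1.81 ± 0.05. In the integrated stress and unfolded protein list, 21 of 34 were higher and 1 lower (22 and 1 adjusted over the list alone). The phosphatase subunit Ppp1r15a (1.77 ± 0.05) and the chaperone Hspa5 (0.77 ± 0.04) were among them. Heat shock genes had 11 of 20 higher and 2 lower (11 and 3 adjusted over the list alone). The co-chaperone Dnajb1 was at 2.28 ± 0.04 and Hspa8 at 0.74 ± 0.04. Mast cell identity genes had 19 of 39 higher and 6 lower (22 and 6 adjusted over the list alone). Hdc, the enzyme that makes histamine, rose by 2.63 ± 0.04 and the tryptase Tpsab1 by 1.66 ± 0.06. The lists of the interleukin 17 pathway (34 higher, 7 lower of 69; 36 and 7 adjusted over the list alone) and of the tumour necrosis factor pathway (42 higher, 10 lower of 94; 44 and 11 adjusted over the list alone) were also called. They share genes such as Fosb, Ccl7, Jun and Csf1 with the lists above and are named in the series title, so they are not independent evidence. All 6 kept their camera call with estimated correlations (adjusted p from 0.00726 to 0.0443). With limma on quantile-normalised values, the heat shock (adjusted p = 0.3365), integrated stress (0.0568) and mast cell identity (0.3365) lists lost it. The mast cell identity list also lost it with limma on the deposited values (0.199) and with total count scaling (0.2545).

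A further 7 lists were called in BSA against Control by camera with the preset correlation but not with an estimated one. Fry also called all 7 (adjusted p from 3.05e-08 to 0.0236), but it called 28 of the 35 lists in this comparison and does not compare a list with other genes. Oxidative stress genes driven by NRF2 had 14 of 27 higher and 0 lower (15 and 0 adjusted over the list alone) (adjusted p = 0.125 with an estimated correlation). Srxn1 was at 2.74 ± 0.05 and the haem-degrading enzyme Hmox1 at 1.19 ± 0.04. Ribosomal protein genes had 35 of 38 higher and 0 lower (38 adjusted over the list alone) at a median of 0.16 (adjusted p = 0.484 with an estimated correlation). This median was -0.07 when libraries were scaled by total count alone. IgE receptor signalling genes had 22 of 61 higher and 6 lower (23 and 6 adjusted over the list alone; adjusted p = 0.0964 with an estimated correlation). The adaptor Lcp2 was at 0.74 ± 0.04, and the list's median of 0.09 became -0.14 under total count scaling. The p53 targets (8 higher, 4 lower of 24; 9 and 5 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation) included Btg2 at 3.27 ± 0.06 and Cdkn1a at 1.74 ± 0.04. That list lost the call without BSA replicate 2 (adjusted p = 0.0641) or 3 (0.0637). Type 2 receptors and costimulatory genes (11 higher, 5 lower of 24; 11 and 5 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation) included Cd69 at 1.99 ± 0.05. They lost the call without BSA replicate 2 (adjusted p = 0.0793). Lysosomal genes (9 higher, 2 lower of 30; 10 and 2 adjusted over the list alone; adjusted p = 0.376 with an estimated correlation) included the autophagy receptor Sqstm1 at 1.18 ± 0.04. They lost the call without Control replicate 1 (adjusted p = 0.0603) or BSA replicate 3 (0.1095). Macrophage markers (5 higher, 2 lower of 16; 7 and 2 adjusted over the list alone; adjusted p = 0.164 with an estimated correlation) included Cd14 at 1.62 ± 0.28 and Lyz2 at 0.57 ± 0.09. They lost the call without Control replicate 1 (adjusted p = 0.0580), Control replicate 3 (0.0790) or BSA replicate 3 (0.0933). With limma on the deposited values, the p53 (adjusted p = 0.0803), ribosomal (0.3165), lysosomal (0.733), type 2 receptor (0.0559) and IgE receptor signalling (0.934) lists lost the call. With quantile normalisation the NRF2 (0.3365), type 2 receptor (0.3365), lysosomal (0.522) and IgE receptor signalling (0.353) lists lost it, and the ribosomal list was called lower (8.56e-07).

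The largest falls after antigen included 6 zinc finger genes. Zfp760 (chromosome 17, 21707741 to 21725636) fell from 13.97 ± 0.871 to 3.21 ± 0.835, and Zfp551 (-2.48 ± 0.32), Zfp870 (-2.25 ± 0.25), Zfp85 (-2.10 ± 0.22), Zfp54 (-2.00 ± 0.19) and Zfp563 (-1.97 ± 0.26) were lower as well. Ccdc39, a component of the ciliary axoneme (-2.49 ± 0.33), the transporter gene Slc16a4 (-2.11 ± 0.30), the potassium channel gene Kcnj2 (-1.99 ± 0.11) and Ankrd61 (-1.97 ± 0.35) completed the 10. The share of higher genes among the called was 47.6% with TMM scaling and 13.6% with scaling by total count, which moved the median of all genes from 0.00 to -0.23 on the log2 scale. It was 69.5% with median centring, which moved that median to 0.10, so smaller fold changes hold relative to the TMM reference. Under total count scaling the medians of the NFAT (-0.07), heat shock (-0.04), integrated stress (-0.07), NRF2 (-0.10), mast cell identity (-0.11), interleukin 17 (-0.02), tumour necrosis factor (-0.09), p53 (-0.14), type 2 receptor (-0.08) and lysosomal (-0.17) lists were also below 0.

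**Figure D1:**
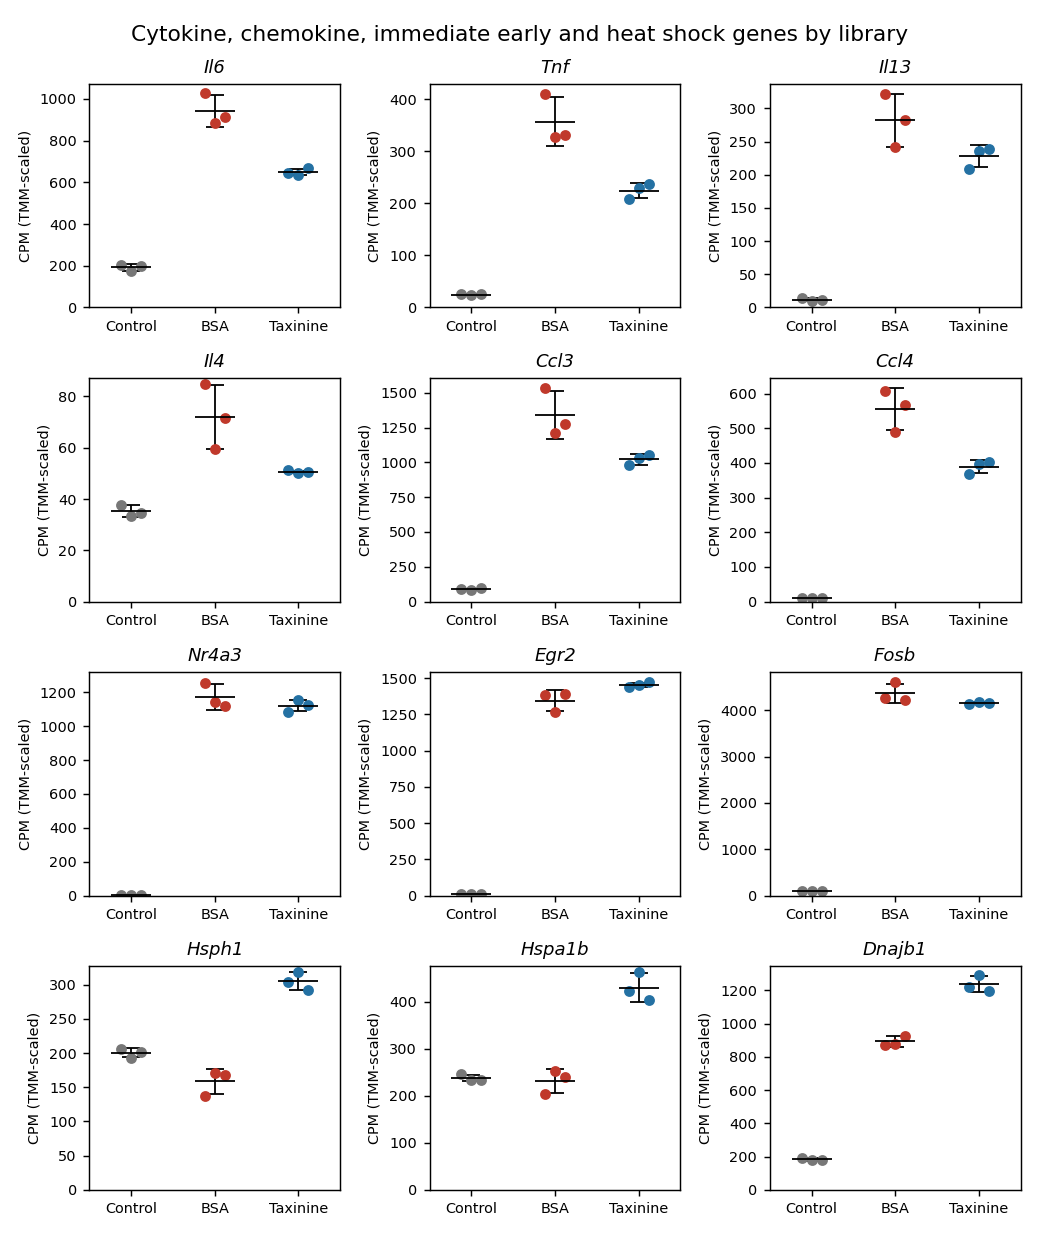
CPM with TMM-scaled totals of cytokine, chemokine, immediate early and heat shock genes in the 9 libraries. Each point is a library, and each bar is the group mean with its SD on a linear axis that starts at 0. Il6, Tnf and Ccl3 were highest in BSA and lower in Taxinine, and Nr4a3 was alike in both activated groups. Hsph1 was highest in Taxinine (305 ± 13.0 against 159 ± 18.6 in BSA).

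The second comparison asks what taxinine changed in cells given the same antigen. Of 20 heat shock genes 12 were called higher in Taxinine than in BSA, and 12 of 20 cytokine and 9 of 17 chemokine genes were called lower. The heat shock list kept its camera call with an estimated correlation (adjusted p = 0.0134), and the cytokine and chemokine lists did not (adjusted p = 0.0554 with an estimated correlation for each). Hsph1, which encodes a chaperone of the HSP110 family (chromosome 5, 149614287 to 149636376), rose from 159 ± 18.6 to 305 ± 13.0, a log2 fold change of 0.94 ± 0.05. Il1b (chromosome 2, 129364570 to 129371139) fell from 207 ± 15.9 to 115 ± 4.87, a log2 fold change of -0.85 ± 0.05. Tnf fell from 356 ± 46.8 to 225 ± 14.5, Il6 from 942 ± 78.1 to 649.6 ± 15.4, and Il4 from 72.0 ± 12.5 to 50.7 ± 0.477. Both receptor genes stayed short of the test, with Fcer1a at -0.07 ± 0.04 and Kit at -0.04 ± 0.04 (edgeR's quasi-likelihood test, adjusted p = 0.270 and 0.629).

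The test called 1055 genes, 432 higher and 623 lower in Taxinine, of which 93 changed at least 1.5-fold and 22 at least 2-fold. The share of higher genes turned with the scaling: it was 40.9% with TMM, 57.6% with total count scaling, 59.2% with limma on the deposited values and 28.5% with median centring. The groups did not overlap in 1028 of them and in 23.9% of all genes, where chance gives 10%. Each Taxinine library moved this count by over 1.5 times: it was 659 without Taxinine replicate 1, 616 without replicate 2 and 699 without replicate 3. It was 781, 1134 and 737 without BSA replicates 1, 2 and 3, so the loss was not particular to the Taxinine libraries. Of the 10 largest rises, 8 kept their call without each of the 9 libraries in turn: the orphan receptor gene Gpr141b (1.39 ± 0.33), the small heat shock gene Hspb1 (1.35 ± 0.21), the Wnt receptor gene Fzd5 (1.06 ± 0.13), Hsph1, Hyls1 (0.91 ± 0.20), Csrnp2 (0.91 ± 0.19), Hspa1a (0.89 ± 0.06) and Hspa1b (0.89 ± 0.05). Of the 10 largest falls, 4 did so: the chemokine gene Ccl1 (-0.93 ± 0.10), the channel subunit gene Kcns1 (-0.92 ± 0.20), the cyclic AMP sensor gene Rapgef3 (-0.90 ± 0.18) and the ribonuclease gene Rnaset2b (-0.89 ± 0.15).

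Of 20 heat shock genes, 12 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.30. Hspa1a and Hspa1b, neighbouring inducible HSP70 genes of nearly identical sequence whose reads cannot be assigned with certainty, reached 120.0 ± 10.9 and 431 ± 30.0 against 64.6 ± 7.04 and 232 ± 25.3. Dnajb1 rose by 0.47 ± 0.04, from 893 ± 30.5 to 1236 ± 48.7. Camera called the list at an adjusted p of 1.35e-12, and at 0.0134 with an estimated correlation. All but 1 of the 12 higher genes, 11, kept their call without each library in turn. In the wider stress lists, the endoplasmic reticulum genes Dnajb9 (0.38 ± 0.05) and Herpud1 (0.26 ± 0.04) rose while Ppp1r15a fell (-0.29 ± 0.05), and that list, with 6 of 34 higher and 1 lower (6 and 1 adjusted over the list alone), was not called. Among NRF2 targets, 4 of 27 rose and 1 fell (5 and 1 adjusted over the list alone), including Gclc, the limiting enzyme of glutathione synthesis (0.43 ± 0.05), Srxn1 (0.23 ± 0.04) and Hmox1 (0.21 ± 0.04). The NRF2 list was called at an adjusted p of 0.0364 by camera (adjusted p = 0.440 with an estimated correlation). Of its calls 3 of the 4 higher and 0 of the 1 lower were kept without each library in turn. The list lost its call without Control replicate 2 (0.0634), BSA replicate 2 (0.177) or Taxinine replicate 3 (0.0835).

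Of 20 antigen-induced cytokines, 12 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.31; 10 of the 12 kept their call without each library. Tnfsf8 fell by 0.64 on the log2 scale (SE 0.06). Il13 fell by 0.30 (SE 0.06) but lost its call without BSA replicate 1 (-0.20; edgeR's quasi-likelihood test, adjusted p = 0.0649). Over all alternatives its adjusted p ran from 1.51e-06 to 0.223. Next to it, Csf2 at -0.71 ± 0.23 missed the threshold (adjusted p = 0.0541, and 0.0164 to 0.301 over the alternatives). Of 17 chemokines, 9 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.38; 8 of the 9 kept their call without each library. Ccl4 (-0.51 ± 0.05), Ccl7 (-0.45 ± 0.05), Ccl3 (-0.39 ± 0.05), Ccl9 (-0.38 ± 0.04) and Ccl2 (-0.32 ± 0.05) were among them, and of 21 lipid mediator genes 3 fell and 0 rose (3 and 0 adjusted over the list alone; adjusted p = 0.0554 with an estimated correlation), Ptgs2 among them (-0.36 ± 0.06); 1 of the 3 kept its call without each library. Camera called the cytokine and chemokine lists, at adjusted p of 7.31e-09 and 4.33e-07, and neither with an estimated correlation (adjusted p = 0.0554 for each).

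In the lists around the signalling that drives these mediators, more genes were called lower than higher. The 5 signalling lists lost their camera call with estimated correlations (adjusted p from 0.0847 to 0.342). In the calcium and NFAT list, 5 of 21 fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.187 with an estimated correlation). Rcan1 was at -0.56 ± 0.06, Nfatc2 at -0.51 ± 0.06 and Nfatc1 at -0.35 ± 0.04. The list lost its call without BSA replicate 1 (adjusted p = 0.0949), Taxinine replicate 1 (0.0566) or Taxinine replicate 3 (0.0662). Among NF-kB targets 10 of 26 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 0.0971 with an estimated correlation). Nfkbid (-0.27 ± 0.04) and Tnip3 (-0.39 ± 0.07) were 2 of these. Among MAP kinase feedback genes 8 of 26 fell and 0 rose (12 and 2 adjusted over the list alone; adjusted p = 0.0940 with an estimated correlation). Rgs2 was at -0.28 ± 0.04 and Pim3 at -0.38 ± 0.06. Among IgE receptor signalling genes 10 of 61 fell and 0 rose (21 and 0 adjusted over the list alone; adjusted p = 0.0847 with an estimated correlation). The adaptors Grap2 (-0.31 ± 0.06) and Lcp2 (-0.19 ± 0.04) and the kinase gene Tec (-0.31 ± 0.06) were lower. Of 30 immediate early genes, 10 fell and 3 rose (11 and 5 adjusted over the list alone; adjusted p = 0.342 with an estimated correlation). Atf3 (-0.49 ± 0.05), Junb (-0.43 ± 0.04) and Jund (-0.40 ± 0.05) fell while Klf10 rose (0.42 ± 0.06). That list lost its call without BSA replicate 1 (adjusted p = 0.0810) or Taxinine replicate 1 (0.0515). The lists named in the series title, and so not independent evidence, had 15 of 69 lower and 2 higher for interleukin 17 (17 and 5 adjusted over the list alone; adjusted p = 0.0716 with an estimated correlation) and 17 of 94 lower and 2 higher for tumour necrosis factor (22 and 3 adjusted over the list alone; adjusted p = 0.0554 with an estimated correlation). The interleukin 17 list lost its call without Taxinine replicate 1 (0.0566) or 3 (0.0662), and Hsp90aa1, a heat shock gene, was 1 of its 2 higher members (0.44 ± 0.04). Of the lower calls, those kept without each library in turn were 3 of 10 for NF-kB targets, 4 of 5 for NFAT, 5 of 8 for MAP kinase feedback and 3 of 10 for IgE receptor signalling. They were 9 of 10 for immediate early genes, 9 of 15 for interleukin 17 and 9 of 17 for tumour necrosis factor.

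Lists outside the mediator and signalling groups were called as well. Progenitor markers had 5 of 11 lower and 0 higher (5 and 0 adjusted over the list alone), including the transcription factor genes Myb (81.3 ± 2.31 to 59.7 ± 2.63, -0.44 ± 0.06) and Meis1 (-0.26 ± 0.06), and kept the call with an estimated correlation (adjusted p = 0.0422). Genes of mitosis had 6 of 36 higher and 0 lower (14 and 1 adjusted over the list alone; adjusted p = 0.0422 with an estimated correlation). The proliferation marker Mki67 was at 0.24 ± 0.05 and had no call once a trend on transcript length and GC content was removed (0.06; edgeR's quasi-likelihood test, adjusted p = 0.366). Cholesterol synthesis and uptake genes had 5 of 25 higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.0554 with an estimated correlation), and 0 of the 5 kept their call without each library in turn. Ribosomal protein genes had 5 of 38 lower (10 adjusted over the list alone; adjusted p = 0.469 with an estimated correlation). Respiratory chain genes had 4 of 38 lower (4 adjusted over the list alone; adjusted p = 0.469 with an estimated correlation). Cox5a was at -0.59 ± 0.10 and Cox5b at -0.35 ± 0.07, and that list lost its call without BSA replicate 3 (adjusted p = 0.0619) and with the GC trend removed (0.438). Macrophage markers had 2 of 16 lower (2 adjusted over the list alone; adjusted p = 0.0940 with an estimated correlation), 1 of them Lyz2 at -0.52 ± 0.10. Basophil markers had 4 of 9 lower (7 adjusted over the list alone; adjusted p = 0.0554 with an estimated correlation), including the protease gene Mcpt8 (-0.35 ± 0.06). Mast cell identity genes had 4 of 39 lower and 0 higher (7 and 0 adjusted over the list alone; adjusted p = 0.0554 with an estimated correlation). Genes of DNA replication had 1 of 34 higher and 1 lower (1 and 1 adjusted over the list alone; adjusted p = 0.148 with an estimated correlation) and lost the call without BSA replicate 2 (adjusted p = 0.1065). Of the calls in these lists, those kept without each library in turn were 3 of 5 for progenitor, 1 of 6 for mitosis, 3 of 5 for ribosomal, 2 of 4 for respiratory chain, 1 of 2 for macrophage, 3 of 4 for basophil and 3 of 4 for mast cell identity genes. The median of the mitosis list was 0.10, and 0.06 with the trend on length and GC content removed. With limma on quantile-normalised values the immediate early (adjusted p = 0.0692), IgE receptor signalling (0.0679), mast cell identity (0.122) and interleukin 17 (0.0616) lists lost their call.

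**Figure D2:**
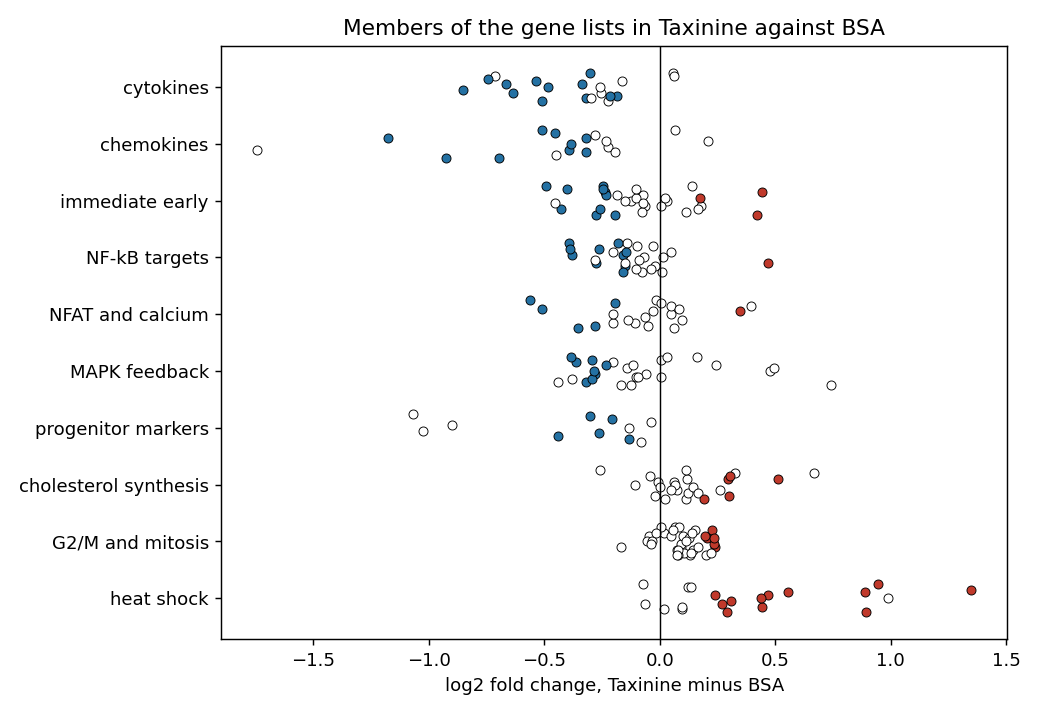
Log2 fold change of the members of the fixed gene lists in Taxinine against BSA; each point is a gene, filled where it was called higher (red) or lower (blue) and white where it was not called. Called heat shock genes lie to the right of 0 (12 of 20), and called cytokine (12 of 20) and chemokine (9 of 17) genes to the left.

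The third comparison asks what remained of the antigen response with taxinine present, measured against untreated cells. Nr4a3 (8.23 ± 0.07), Egr2 (7.04 ± 0.06), Nr4a1 (6.00 ± 0.06), Egr3 (5.89 ± 0.06) and Fosb (5.35 ± 0.05) were again among the most raised genes. Tnf (3.18 ± 0.07), Il6 (1.76 ± 0.05), Il13 (4.30 ± 0.09), Il4 (0.52 ± 0.08) and Il1b (0.46 ± 0.05) were still above Control. Of 20 antigen-induced cytokines 19 were higher (20 adjusted over the list alone), and of 30 immediate early genes 27 were higher and 2 lower (27 and 2 adjusted over the list alone). Heat shock genes had 17 of 20 higher and 0 lower (17 and 0 adjusted over the list alone) at a median of 0.73, with Dnajb1 at 2.75 ± 0.04, Dnaja1 at 1.27 ± 0.04 and Hspa8 at 1.01 ± 0.04. Genes of mitosis had 18 of 36 higher and 0 lower (20 and 0 adjusted over the list alone), with Cenpf at 0.52 ± 0.06 and Cdc20 at 0.47 ± 0.07, and the list's median of 0.18 became -0.02 under total count scaling. Cholesterol genes had 10 of 25 higher and 1 lower (10 and 1 adjusted over the list alone), including Cyp51 (0.78 ± 0.08). These 5 lists kept their camera call with estimated correlations (adjusted p from 0.00798 to 0.0290). The largest falls included Zfp551 (-2.17 ± 0.32), Slc16a4 (-2.12 ± 0.31), the transcriptional repressor gene Gfi1 (-1.97 ± 0.25), B3gnt7 (-1.90 ± 0.18) and Zfp128 (-1.86 ± 0.20).

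Further lists above Control were the MAP kinase feedback genes (20 of 26 higher, 3 lower; 20 and 4 adjusted over the list alone), glucose metabolism and hypoxia (20 of 28 higher, 1 lower; 20 and 1 adjusted over the list alone) and integrated stress (21 of 34 higher, 2 lower; 21 and 3 adjusted over the list alone). The interleukin 17 list (34 of 69 higher, 6 lower; 37 and 7 adjusted over the list alone) and the tumour necrosis factor list (40 of 94 higher, 16 lower; 43 and 16 adjusted over the list alone) were called too, and all 5 kept the call with estimated correlations (adjusted p from 0.00798 to 0.0475). Other lists were called by camera with the preset correlation but not with an estimated one. All of them except the ribosomal list (fry, adjusted p = 0.320) were also called by fry. They were chemokines (10 of 17 higher, 1 lower; 10 and 1 adjusted over the list alone; adjusted p = 0.0791 with an estimated correlation), NF-kB targets (17 of 26 higher, 6 lower; 18 and 6 adjusted over the list alone; adjusted p = 0.0638 with an estimated correlation) and the NFAT list (8 of 21 higher, 2 lower; 9 and 2 adjusted over the list alone; adjusted p = 0.0871 with an estimated correlation). NRF2 targets (14 of 27 higher, 0 lower; 14 and 0 adjusted over the list alone; adjusted p = 0.104 with an estimated correlation) and lysosomal genes (9 of 30 higher, 1 lower; 9 and 1 adjusted over the list alone; adjusted p = 0.329 with an estimated correlation) belong here too. Mast cell identity genes (16 of 39 higher, 8 lower; 18 and 8 adjusted over the list alone; adjusted p = 0.110 with an estimated correlation) lost the call without Control replicate 1 (adjusted p = 0.0691), Control replicate 3 (0.0503) or Taxinine replicate 1 (0.0697). Ribosomal protein genes (9 of 38 higher, 0 lower; 3 and 0 adjusted over the list alone; adjusted p = 0.846 with an estimated correlation) lost it without Control replicate 1 (0.2999), Control replicate 3 (0.109) or Taxinine replicate 3 (0.124). Progenitor markers (0 of 11 higher, 2 lower; 0 and 1 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation) lost it without Control replicate 1 (0.0679), Control replicate 3 (0.0754), BSA replicate 2 (0.0503) or Taxinine replicate 3 (0.118). With total count scaling the medians of the NFAT (-0.08), mast cell identity (-0.13), interleukin 17 (-0.05), tumour necrosis factor (-0.08), NRF2 (-0.03), integrated stress (-0.00347), ribosomal (-0.14) and lysosomal (-0.12) lists lay below 0, and that of the cholesterol list was 0.01 against 0.21. With limma on the deposited values the mitosis (adjusted p = 0.0971), mast cell identity (0.673), ribosomal (0.393) and lysosomal (0.738) lists lost their call. With quantile normalisation the mast cell identity (0.0732) and lysosomal (0.853) lists lost it, and the ribosomal list was called lower (2.47e-09).

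In all, edgeR's quasi-likelihood test called 5008 genes in Taxinine against Control, 2407 higher and 2601 lower, with 858 at least 2-fold. The groups did not overlap in 4739 of them and in 43.7% of all genes, where chance gives 10%. The share of higher genes was 48.1% with TMM scaling and 15.0% with total count scaling, which moved the median of all genes from -0.01 to -0.21. With median centring it was 66.1%, at a median of 0.07.

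As a share of the rise in BSA over Control, the rise left with taxinine was 25.5% for Il1b, 41.8% for Il4, 60.2% for Tnf, 61.1% for Il6, 69.6% for Ccl4, 74.5% for Ccl3 and 80.1% for Il13. Csf1 kept 87.0%. Not every mediator gene lost part of its rise: Vegfa kept 106.3%, Cxcl10 105.8% and Tnfsf9 105.7%. These genes were chosen after their values were seen. Transcription factor genes overlapped the values of the mediator genes, with 67.6% for Jund, 69.8% for Atf3 and 70.2% for Junb. Nr4a1 kept 82.5%, Fosb 95.1%, Nr4a3 95.6% and Egr2 108%. Of the 556 genes at least 2-fold higher in BSA than in Control, 122 were called lower in Taxinine than in BSA and 26 higher, with a median of 82.9% of the rise left. Of the 384 genes at least 2-fold lower in BSA, 22 were called higher in Taxinine and 0 lower, with a median of 85.6% of the fall left. Both sets were picked by their BSA level, which also enters the share left. Noise in the BSA libraries alone therefore lowers both medians and favours opposed calls, and neither was set against a simulation. Over all calls, 520 genes were called in opposite directions in BSA against Control and Taxinine against BSA: 343 higher then lower, and 177 lower then higher. Independent lists of these sizes would share 101.02 and 77.03 genes. In 100 simulated sets of unchanged groups at most 1 gene was opposed, but no simulated comparison called over 3 genes, so these counts do not measure what the shared BSA libraries add. The covariance over genes was -0.104 against a simulated -0.0684 (-0.0788 to -0.0600). The correlation was -0.346 against a simulated -0.511. The shared BSA libraries alone give this simulated value, and these sets lack the antigen response, so the correlations are not comparable. In simulated sets that kept the antigen response and had no taxinine effect, the covariance was -0.0707 (-0.0819 to -0.0564) and the correlation -0.235 (-0.265 to -0.192). The observed values lay below both ranges, but variation within a library that is common to many genes was not simulated. The count of opposed genes was 336 without Taxinine replicate 1 and 312 without Taxinine replicate 2.

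BSA and Taxinine against Control shared 1762 higher and 1909 lower genes, where independent lists would share 390 and 464, and 16 genes were opposed. Simulated unchanged groups shared at most 1 gene, which their few calls fixed beforehand. The covariance was 0.384 against a simulated 0.0531 (0.0480 to 0.0617), and the correlation 0.806 against 0.419. With 3 libraries the shared groups cannot be split into parts of at least 2, so part of either excess may come from the shared libraries.

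**Figure D3:**
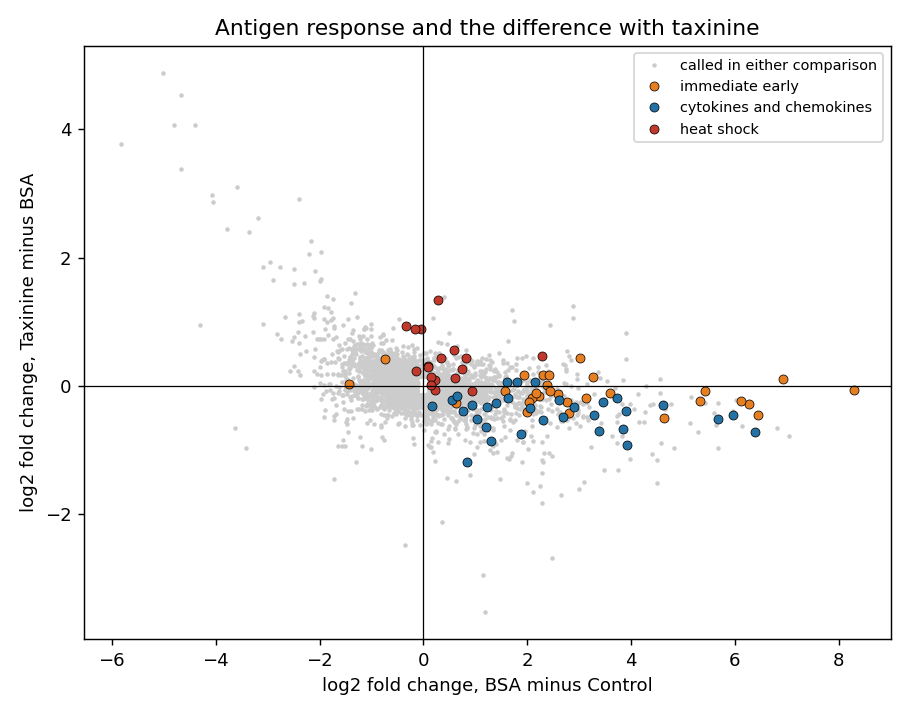
Log2 fold change of BSA against Control (horizontal) and of Taxinine against BSA (vertical) for genes called in either comparison; each point is a gene, and fold changes of genes with no counts in a group depend on the prior count. Most genes at least 2-fold higher in BSA lie below 0 on the vertical axis (74.5% of 556); the 2 axes share the BSA libraries, which alone gives a negative covariance.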

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

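Library scaling moved the direction of small changes. Leaving out any Taxinine library, or BSA replicate 1 or 3, lowered the number of calls in Taxinine against BSA, and the cause was not tested. With limma on the deposited log2 values, as planned, 7852 genes were called in BSA against Control, 7852 with a pseudocount of 0.5, 7842 with 5, and edgeR with total count scaling called 7977. In these 4 settings Fcer1a was at -0.19 and Kit at -0.15 in BSA against Control, and Kit at -0.17, -0.17, -0.16 and -0.17 in Taxinine against Control. The median of the IgE receptor signalling list in BSA against Control was -0.14, -0.14, -0.13 and -0.14, and that of the ribosomal list in Taxinine against Control was -0.14 in each. With quantile normalisation Fcer1a was at -0.32 and Kit at -0.45 in BSA against Control, and Kit at -0.43 in Taxinine against Control. List medians were then -0.0595 for IgE receptor signalling, -0.0437 for mast cell identity, -0.22 for ribosomal and -0.0815 for lysosomal genes in BSA against Control. In Taxinine against Control they were -0.0310 for mast cell identity, -0.25 for ribosomal and -0.0326 for lysosomal genes.

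In the order BSA against Control, Taxinine against BSA and Taxinine against Control, 1808, 93 and 1648 called genes changed at least 1.5-fold, and 940, 22 and 858 at least 2-fold. An unadjusted p under 0.05 with a 2-fold change gave 1092, 192 and 1044. Camera with estimated correlations called 12, 3 and 10 lists, and fry called 28, 22 and 26. In Taxinine against BSA, fry did not call the immediate early (adjusted p = 0.0560), ribosomal (0.152) or respiratory chain (0.157) lists. Of the opposed genes, 39 changed at least 1.5-fold in both comparisons. Leaving out each library gave 616 to 1281 genes in Taxinine against BSA (659 without Taxinine replicate 1, 616 without 2, 699 without 3) and 312 to 609 opposed genes (336 without Taxinine replicate 1, 312 without 2). It gave 4454 to 5070 genes in BSA against Control and 4221 to 5130 in Taxinine against Control. Lists ranged from 16 to 19, 18 to 22 and 15 to 20. The alternative without a filter was void because the planned filter removes no gene, and list tests were not run under DESeq2, thinning and the other filters.

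With the replicate number as a replicate block, 5078, 1093 and 4972 genes were called, with 17, 21 and 17 lists and 531 opposed genes. The lists of p53 targets (adjusted p = 0.0578) and type 2 receptors (0.0515) in BSA against Control and of mast cell identity in Taxinine against Control (0.0564) lost their call by camera. No sign of pairing by number was seen: correlations of libraries with the same number ran from -0.248 to 0.133, and the own number was best in 2 of 9 cases. Counting noise and differences between libraries could hide a weak pairing, so this check does not exclude it.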

Other observations

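Several processes that mast cell activation might engage gave no list call by camera in BSA against Control, although single members changed. Fry called the lists of granule secretion (adjusted p = 6.8e-05), DNA replication (0.0020), apoptosis (0.0020) and tubulin (0.0087). Fry did not call the interferon list (adjusted p = 0.506). Genes of the granule secretion machinery had 9 of 36 higher and 8 lower (10 and 8 adjusted over the list alone), with the adhesion receptor Adgre5 at 1.38 ± 0.04 and the vesicle tether Sytl3 at 0.79 ± 0.05. Interferon response genes had 4 of 27 higher and 5 lower (4 and 5 adjusted over the list alone): the antiviral genes Isg15 (1.24 ± 0.17) and Rsad2 (0.90 ± 0.07) rose while Stat2 (-0.79 ± 0.08) and Usp18 (-0.54 ± 0.08) fell. DNA replication genes had 5 of 34 higher and 5 lower (5 and 5 adjusted over the list alone), with the polymerase clamp Pcna at 1.58 ± 0.04 and the cyclin gene Ccne2 at -0.64 ± 0.10. Apoptosis genes had 6 of 23 higher and 7 lower (6 and 7 adjusted over the list alone), with the survival gene Mcl1 at 1.28 ± 0.04 and the death-promoting gene Bmf at -0.85 ± 0.06. Tubulin and microtubule genes, of interest because other taxanes bind tubulin, had 8 of 22 higher and 4 lower in BSA (8 and 4 adjusted over the list alone).

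In Taxinine against BSA, 1 of the 22 tubulin and microtubule genes was called higher and 0 lower (1 and 0 adjusted over the list alone). Targets of p53 had 5 of 24 higher and 1 lower (7 and 3 adjusted over the list alone), and granule secretion genes had 1 of 36 higher and 3 lower (2 and 7 adjusted over the list alone). Camera called none of these 3 lists. Fry called the p53 (adjusted p = 0.0115) and granule secretion (0.00215) lists but not the tubulin list (0.211). Among markers of other cells, 0 of 6 lymphocyte, 0 of 6 neutrophil and 0 of 10 erythroid and megakaryocyte genes were called in Taxinine against BSA. Called lower were 5 of 11 progenitor, 4 of 9 basophil, 2 of 16 macrophage and 1 of 7 dendritic cell genes.

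The patterns described here were picked from the results, and the zinc finger group and its scaling test, the test on the share of responding cells, the simulations that keep the antigen response and the tests on the GC trend were chosen after the results were seen. The median of the heat shock list with taxinine changed little in each of the 3 tests run on it. The lowest list median was 0.28 over 4 other library scalings and 0.29 without 1 Taxinine or BSA library. After a trend of the fold changes on transcript length and GC content was removed it was 0.32. The 4 scalings moved the median of all genes in this comparison only to between -0.02 and 0.03. The fitted trend at the heat shock genes had a median of 0.00127. The scaling and trend tests therefore had little room to fail. A response of the cells to taxinine that raises chaperone transcripts is a hypothesis consistent with these values. A group with taxinine alone was not analysed here, so an effect that needs antigen stays open.

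The lower cytokine and chemokine transcripts with taxinine could come from fewer responding cells. If each responding cell raises all strongly induced genes alike, these genes would fall by a like amount. Among genes induced at least 8-fold, the mean log2 fold change was -0.12 for 12 immediate early genes and -0.50 for 11 cytokine and chemokine genes, and a two-sided permutation test of the difference gave p = 0.00072. The permutation treats genes measured in the same libraries as independent, so its p does not measure variation between libraries. A smaller responding share as the whole cause predicts no such gap only if each responding cell raises both sets alike, which was not tested. Values ran from -0.49 (Atf3) to 0.44 (Klf4) for immediate early genes and from -0.93 (Ccl1) to -0.18 (Csf1) for the others. Some genes had few counts, with 31, 11 and 30 in BSA for Egr4, Ccl12 and Il10. Different timing of the response and variation between libraries that these genes share stay open. Because the BSA libraries are shared, the covariance over the cytokine list, -0.0838, was set against simulations. It lay below unchanged groups (lowest -0.0724), but these lack the antigen response, and with that response kept the range was -0.189 to 0.121, so this covariance decides nothing. In the same simulations the list median for Taxinine against BSA ran from -0.0435 to 0.0493, against an observed -0.31, so noise that is independent between genes does not give a fall of this size. Variation within a library that is common to these genes was not simulated and stays open. With the length and GC trend removed the list median was -0.27.

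Genes named Zfp with a number, 318 of them without Zfp36, were lower in BSA than in Control: 186 were called lower and 19 higher, with a median of -0.47. Over 4 other library scalings the set median nearest 0 was -0.37, and with the length and GC trend removed the set median was -0.50. The lowest median of 10000 random lists matched on expression was -0.13, so low counts did not account for it. With taxinine, 20 were called higher and 8 lower than in BSA (median 0.10). No biological explanation was tested.

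A trend with GC content was seen in Taxinine against BSA. Across 10154 genes, which are not independent replicates, Spearman's coefficient between fold change and GC content was -0.227, against -0.0486 for BSA against Control and -0.166 for Taxinine against Control. The coefficient for each library's deviation from the gene's mean over the 9 libraries varied within groups. It was 0.00430, 0.215 and 0.0580 in Control, -0.0662, -0.0322 and 0.238 in BSA, and -0.255, -0.122 and -0.158 in Taxinine replicates 1 to 3. Genes called higher in Taxinine against BSA had a median GC content of 46.0% and those called lower 52.1%. With the trend removed within each library, 1339 genes were called in this comparison, 904 of them shared. List medians in Taxinine against BSA moved from 0.10 to 0.06 for mitosis, from 0.07 to 0.04 for NRF2 targets, from -0.09 to -0.03 for ribosomal, from -0.04 to -0.01 for respiratory chain and from -0.05 to -0.09 for NFAT genes. The lists of respiratory chain genes (adjusted p = 0.438) and immediate early genes (0.124) then lost their call by camera, while 14 heat shock genes were higher and 1 lower, and 12 cytokine genes were lower.

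Other splits of the same 6 libraries were counted for each comparison. In fits of these libraries alone the real split called 4917 genes for BSA against Control, 1177 for Taxinine against BSA and 5222 for Taxinine against Control, and the highest other split called 0 in each. The real split was the 1 of 10 with as many genes in each case. With 3 libraries against 3, 10 splits cannot give a share under 0.1.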
